A study of Mus musculus with 6 samples.

How the data were processed

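RNA immunoprecipitation followed by sequencing (RIP-seq) was used on the anterior cingulate cortex of adult wild-type mice, with an antibody against YTHDF1, a cytoplasmic protein that binds N6-methyladenosine (m6A) in messenger RNA. There were 6 libraries: 3 immunoprecipitated (IP) and 3 input libraries, numbered 1 to 3. The design text calls the replicates biologically independent. The titles of the replicate 2 libraries name no tissue or genotype, unlike those of replicates 1 and 3; their other labels give the same tissue and genotype as for the rest. Per the labels' protocols, cortex was lysed in a polysome buffer, a part of the supernatant was kept as input, the rest was incubated with antibody-coupled beads, and libraries were made with SMART-Seq v4, a full-length cDNA kit for small amounts of RNA. The protocol names no crosslinking and no shearing of RNA before the precipitation, so a whole transcript can be pulled down through any site, and the place of a peak need not be the place that was bound. No IgG or Ythdf1-knockout precipitation is among the libraries analysed here, so binding to beads or antibody is not subtracted beyond the input.

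The deposited files are peak lists made by the authors, 1 per replicate, each setting the IP library against the input of the same number; replicates were not pooled. The lists of replicates 1 and 3 share a format. Per the file headers, they give for each peak a log2 fold of IP over input, a p-value and a Benjamini-Hochberg adjusted p-value, a region label and an Ensembl gene with its span, and peaks can bridge introns. The list of replicate 2 is of another kind: per the file headers, the authors' values there are a linear fold (a ratio of IP over local background) at the summit, the −log10 of p and of q, and a pileup signal at the summit in the IP library, with no gene, region or strand. Per the submitters' processing notes, the tools were fastp 0.20.1, HISAT2 2.1.0, bedtools 2.29.2, HOMER 4.11.1, StringTie 1.3.3b and DESeq 1.38.0, without their roles. The peak caller, its settings and the genome build are not given in the sources used here. All folds, p-values and q-values of single peaks below are the authors' and were used only to describe, rank or filter peaks within a list. Read counts per library and sequencing depth are not given in the files, so depth is unknown and intervals on shares of peaks or genes cover counting error only. In the list of replicate 2, pileups were multiples of 0.73, from 3 such steps at the lowest peak to a median of 14 steps, and 22.8% of peaks stood at 5 steps or fewer.

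Starts in the lists of replicates 1 and 3 counted from 0, as 2908 and 3258 peaks began 1 base before the first base of their gene and 0 began on it; all coordinates are given 1-based. Of 13127 gene names in these lists, 12418 matched a symbol or a unique synonym of the RefSeq annotation of GRCm38.p6, and the spans of all 11477 protein-coding genes compared overlapped those of RefSeq. That annotation was used for names, biotypes and gene order, and for the spans of genes that the lists of replicates 1 and 3 do not name. Such spans served to assign summits of replicate 2, to place its peaks at random and to form strata of gene span. The spans given here are those of the files. For replicate 2, a peak was given to a gene when its summit lay in the span of 1 protein-coding gene, which held for 34728 peaks. Another 1536 summits lay in several such genes and were not assigned, and 3777 lay in none. The share of summits in a protein-coding span was 90.6% and fell to 46.8% when every summit was moved by 1000000 bp. Because that list carries no strand, and the kit does not mark strand, peaks there and overlapping or antisense genes cannot be told apart. Analyses of genes cover 21887 protein-coding genes.

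Peak overlap was counted at a minimum of 1 bp for each ordered pair of lists and set against 100 random placements of each peak within the span of its gene. The count of genes with a peak in all 3 lists was set against 10000 draws of independent lists within 10 strata of gene span. Before the data were examined, 16 gene lists were fixed: actin turnover, excitatory postsynapse, presynaptic release, GABAergic synapse, m6A machinery, activity-regulated, stress and monoamine signalling, chromatin and transcription regulators, cytosolic ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded genes (respiratory chain subunits and both ribosomal RNAs), and markers of cortical excitatory neurons, astrocytes, oligodendrocyte lineage, microglia and macrophages, and vascular and meningeal cells. For each, Fisher's exact test (two-sided) compared members with a peak in all 3 lists with other members that had a peak in any list, against all other genes with a peak, adjusted over lists by Benjamini-Hochberg at 0.05. A rank test compared the median percentile of the members' best peak fold within a list with 10000 random gene lists, and a list was called only when all 3 replicates passed in 1 direction. Percentiles are within a list. The best fold is the highest over a gene's peaks, so it can rise with their number, and the random lists were not matched on that number. Also fixed beforehand was the rule for named genes: Cap1 and Ythdf1; the 10 genes with a peak in all 3 lists and the highest mean percentile of best peak fold, for symbols with 1 annotated gene; up to 4 such members per gene list; and, for lists with fewer members or none in all 3, up to 2 members without a peak, in alphabetical order. Any other gene named is said to be chosen after its values were seen, and 2 genes that the rule selects are not reported here.

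Alternatives covered stricter peak thresholds, list lengths, the overlap required, gene assignment, the background, matching on gene span, the measure ranked and leaving out each replicate. The planned tests of IP against input per gene could not be run, because the lists analysed here hold no values per library; those of the m6A motif and of exon positions need a genome sequence and exon annotation, not used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap code was checked against bedtools 2.31.1 and differed in 0 of 12 counts. The list test was tested on simulated data with 13095 genes and lists of 50 members: it called 96% of lists raised from 64% to 90%, 98% of lists lowered to 35% and 1% of unchanged lists. Adjustment there ran over 200 lists, 100 of them unchanged. The real test was adjusted over 15 lists, several of them shorter, so these rates need not hold for it. The rank test called 0 of 19 unmoved lists. Its simulated replicates were independent, unlike replicates 1 and 3, and how often it calls a moved list was not measured.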

Results

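The study set out to find the messenger RNAs that YTHDF1 binds in the anterior cingulate cortex, a frontal area of the brain linked to mood and anxiety. Its title names CAP1, a protein that recycles actin monomers, as a mediator. Each of 3 replicates gave 1 list of peaks where the YTHDF1 precipitate exceeded the input. Replicate 1 had 28464 peaks, replicate 2 had 40041 and replicate 3 had 28631. These fell in 10597, 11118 and 10739 protein-coding genes. Peaks of replicates 1 and 3 were alike in size and strength, with median spans of 781.5 and 832 bp, introns included, and median log2 folds of 1.37 and 1.36. Those of replicate 2 had a median span of 264 bp and a median log2 fold of 1.66, from another kind of list. The highest p was 0.0500, 0.0498 and 0.0500 in the lists of replicates 1, 2 and 3. At a q or adjusted p under 0.05, 98.3% and 98.0% of the peaks of replicates 1 and 3 were left, and 55.3% of those of replicate 2. Sequencing depth is unknown, so differences in the number of peaks cannot be set against it.

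A peak was found in all 3 lists for 8427 genes, 64.4% of the 13095 protein-coding genes with a peak in any list. Independent lists drawn within strata of gene span would share 3882 genes, and the observed number was 2.17 times that (one-sided permutation test, p = 0.0001, the smallest the draws can give). Those draws came from all 21887 protein-coding genes, also those that may not be expressed in this tissue, so the excess need not reflect binding. Among genes with any peak the expectation was 7452, which the observed number exceeded 1.13 times. For pairs of lists within strata of gene span, the ratio to independent lists was 1.61 for replicates 1 and 3, 1.42 for 1 and 2 and 1.40 for 2 and 3. Among genes with any peak it was 1.13 for replicates 1 and 3, 0.994 for 1 and 2 and 0.986 for 2 and 3. Leaving out genes without a peak in any list lowers these ratios by construction, so values near 1 do not show a lack of sharing. Genes seen in a single list numbered 225 for replicate 1, 1618 for replicate 2 and 320 for replicate 3. Replicates 1 and 3 shared 9859 genes, replicates 1 and 2 shared 8940, and replicates 2 and 3 shared 8987. At a fold of 4 or more the number of genes in all 3 lists was 1330, and at a q or adjusted p under 1e-5 it was 4227.

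Peaks also overlapped more often than at random. On average over both directions, 78.1% of the peaks of replicates 1 and 3 overlapped, against 40.0% after random placement within the same genes. For replicates 1 and 2 the overlap was 49.2% against 25.6%, and for replicates 2 and 3 it was 48.6% against 24.8%. Each pair thus overlapped 1.92 to 1.96 times as often as placed at random (one-sided permutation test, p = 0.0099, the smallest that 100 placements can give), and single directions ranged from 1.63 to 2.34 times. These overlaps are of 1 bp or more between spans that can bridge introns. With an overlap of 50% of both peaks, the shares were 47.7% against 10.6% for replicates 1 and 3, 8.10% against 1.51% for replicates 1 and 2 and 7.82% against 1.45% for replicates 2 and 3 (one-sided permutation test, p = 0.0476, the smallest that 20 placements can give). Random placement included introns, so the excess is not corrected for the place of exons.

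The highest best peak folds over all 3 lists are given for 10 genes, among which no gene group was tested. The highest mean percentile, 99.0, belonged to E130308A19Rik, an uncharacterised gene, with best log2 folds of 6.43, 4.93 and 3.65 in replicates 1, 2 and 3. S1pr1, a receptor for sphingosine-1-phosphate, had 3.99, 4.35 and 3.52, with overlapping peaks on chromosome 3, at 115711958 to 115715072 in replicate 1 and 115712614 to 115713286 in replicate 2. Rbm15, which recruits the m6A methyltransferase complex to RNA, had 7.09, 3.47 and 6.20. The strongest Rbm15 peak lay in a coding exon on chromosome 3 from 107330976 to 107331150 in replicate 1, with an adjusted p of 0.00057, and in an intron in replicate 3. Dnm1, the dynamin of synaptic vesicle retrieval, had best log2 folds of 4.03, 4.64 and 3.03, and Grik5, a kainate receptor subunit, had 3.42, 4.33 and 3.34. For Grik5 the best peaks of all 3 lists lay at one place, on chromosome 7 from 25009849 to 25010573 in replicate 1, in the 3' UTR. The deubiquitinase gene Otud7a had 3.32, 4.25 and 3.77, with peaks over its stop codon on chromosome 7. Gak, a kinase of clathrin uncoating, had 4.04, 4.12 and 3.23, and Scn4b, a sodium channel beta subunit, had 4.47, 3.61 and 3.48. Zfp87, which encodes a zinc finger protein, and Otulin, which encodes a deubiquitinase of linear ubiquitin chains, completed these 10 genes with mean percentiles of 97.5 and 97.4. A high fold can rest on few reads, and the order among these 10 genes was not tested.

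Cap1 had a peak in all 3 lists, each among the weaker ones. The gene spans 122859047 to 122886056 on chromosome 4, minus strand (ENSMUSG00000028656). Replicate 1 held 1 peak in the 3' UTR, from 122859297 to 122859396, with a log2 fold of 1.03 and an adjusted p of 0.0356. Replicate 2 held 2 peaks, the stronger from 122859531 to 122859924 with a fold of 3.01, a log2 fold of 1.59 and a q of 0.0929. Replicate 3 held 1 peak over the stop codon, from 122859772 to 122861937 including introns, with a log2 fold of 0.94 and an adjusted p of 0.0239. By fold, these best peaks stood at percentiles 4.34, 19.8 and 2.57 of the genes in their lists. The peaks of replicates 2 and 3 overlapped, and that of replicate 1 lay apart from both, nearer the 3' end of the gene. At a q or adjusted p under 0.05 in every list Cap1 had a peak in 2 lists, and at a fold of 4 or more or under 1e-5 in 0.

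Ythdf1, the gene of the precipitated protein, had stronger peaks in all 3 lists (ENSMUSG00000038848, chromosome 2, minus strand, 180904377 to 180920949). Replicates 1 and 3 each had 1 wide peak labelled as over the stop codon, spanning 7593 and 7368 bp from the 3' end of the gene, introns included. Log2 folds of these peaks were 1.80 and 1.69, with adjusted p-values of 5.7e-86 and 2.2e-98, at percentiles 58.1 and 52.2. Replicate 2 had 3 peaks. Its strongest lay at the 5' end, from 180920535 to 180920911, with a fold of 9.09 and a q of 9.7e-12, at percentile 90.3, and another, from 180904961 to 180905413 with a log2 fold of 1.71, lay inside the peaks of replicates 1 and 3. Ythdf1 kept a peak in 3 lists under 1e-5 and in 1 list at a fold of 4 or more.

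**Figure D1:**
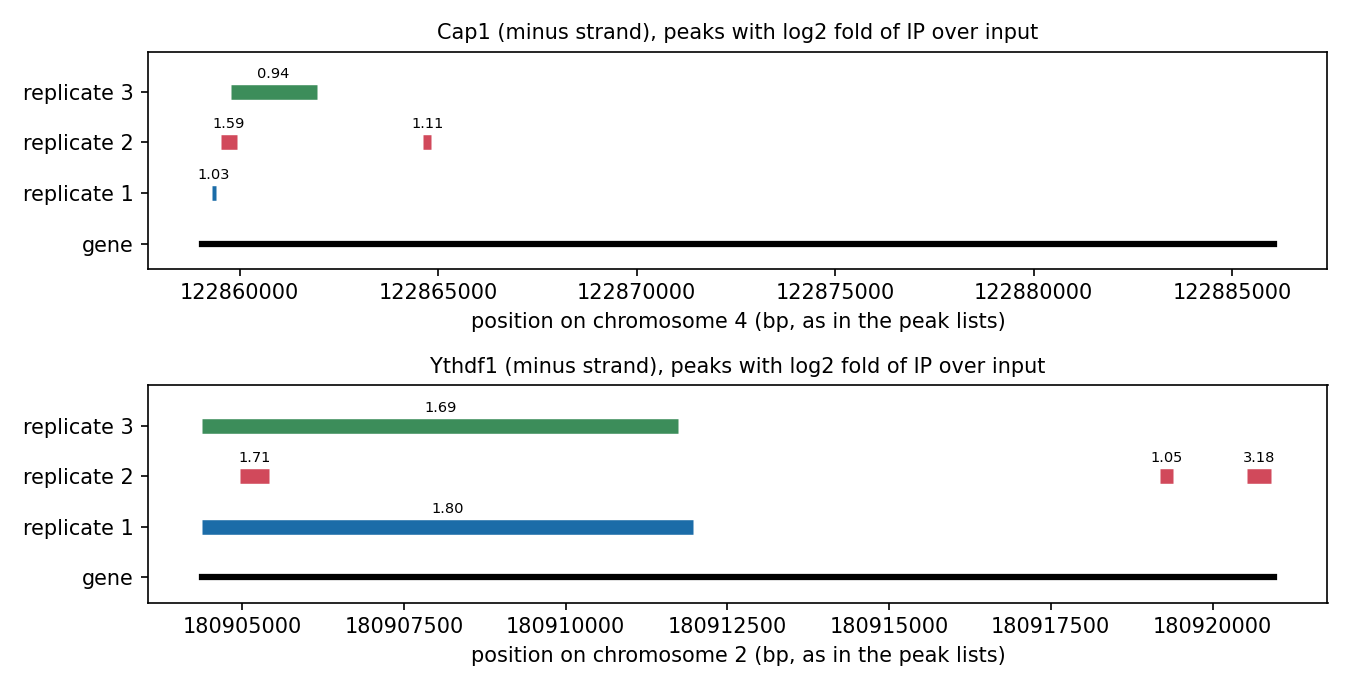
Peaks in Cap1 (upper panel) and Ythdf1 (lower panel) by position in bp along the chromosome; the black bar is the gene span, coloured bars are peaks of each replicate with introns they bridge, and the number above each is its log2 fold of IP over input. Cap1 peaks have log2 folds from 0.94 to 1.59 and lie mostly at the 3' end, on the left for these minus-strand genes.

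Chromatin and transcription regulators, a list of histone modifiers, remodellers and coactivators, were the fixed list with the highest share of members in all 3 lists. Of 53 members with a peak, 51 had one in all 3 lists (96.2%, exact 95% interval 87.0 to 99.5), against 64.2% of other genes (odds ratio 14.2, 3.73 to 121, Fisher's exact test, adjusted p = 7.6e-07). Best log2 folds were 3.73, 3.52 and 4.45 for Ep300, a histone acetyltransferase, and 3.34, 5.28 and 2.71 for Hdac4, a histone deacetylase. For the remodeller gene Chd8 they were 2.84, 3.56 and 3.94, and for the cofactor gene Ankrd11 they were 3.10, 3.20 and 3.34. The median percentile of the list's best folds was 86.7, 66.1 and 82.5. Adjusted p-values were 0.0030, 0.055 and 0.0030 (permutation test against random lists), so replicate 2 missed the threshold. The random lists were not matched on the number of peaks per gene, which can raise a best fold. Between replicates 1 and 3 alone, the difference in presence was not past the threshold either (Fisher's exact test, adjusted p = 0.14).

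Stress and monoamine signalling genes were also found more often in all 3 lists, 31 of 36 (86.1%, odds ratio 3.44, 1.33 to 11.3, Fisher's exact test, adjusted p = 0.0187). Adra2c, an alpha-2 adrenergic receptor, had best log2 folds of 4.16, 3.46 and 3.63, with peaks over the stop codon on chromosome 5. Ntrk3, a neurotrophin receptor, had 3.07, 3.34 and 2.72, and Oprl1, the nociceptin receptor, had 2.65, 3.14 and 2.66. For Nr3c1, the glucocorticoid receptor, the values were 2.48, 2.66 and 6.48. Their median percentiles of best fold, 57.5, 59.7 and 56.8, did not differ from random lists in any replicate. The difference in presence was lost in 10 of the 16 alternatives, among them the higher-fold 50% of each list (Fisher's exact test, adjusted p = 0.70), replicates 1 and 3 alone (adjusted p = 0.77) and replicates 1 and 2 alone (adjusted p = 0.12).

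Cytosolic ribosomal protein genes were less often in all 3 lists. Of 78 members, 43 had no peak in any list, among them Rpl10 and Rpl12, and 8 of the 35 with a peak had one in all 3 lists (22.9%, 10.4 to 40.1, odds ratio 0.163, Fisher's exact test, adjusted p = 6.2e-06). Replicates 1, 2 and 3 held 15, 28 and 17 members. Rps6 had best log2 folds of 0.97, 2.59 and 1.09, Rpl18 1.02, 2.63 and 1.00, and Rpl11 1.12, 1.82 and 1.38. Rpl5 had 1.47, 2.24 and 3.79, the last from a peak in an intron. The list's median percentiles of best fold were 16.9, 29.0 and 9.36, with adjusted p-values of 0.0142, 0.055 and 0.0030, so again replicate 2 missed the threshold. Ranked by the p of the best peak, they were lower than random lists in replicates 1 and 3 (18.2 and 21.8) and higher in replicate 2 (77.8, permutation test, adjusted p = 0.0125, 0.0157 and 0.0024). Many of these genes have near-identical pseudogenes, and how the authors placed reads that fit both is not given in the sources used here.

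Nuclear-encoded respiratory chain genes were also less often in all 3 lists, 19 of 54 (35.2%, 22.7 to 49.4, odds ratio 0.299, Fisher's exact test, adjusted p = 1.0e-04). Of all 70 members, replicate 2 held 49, and replicates 1 and 3 held 22 and 26. Atp5e and Atp5h were among the 16 members without a peak. Ndufs1, of complex I, had best log2 folds of 1.96, 3.26 and 1.97, and Uqcrc1, of complex III, had 1.91, 2.89 and 1.67. Sdhb, of complex II, had 2.40, 1.81 and 2.04, and Ndufa10 had 1.27, 2.73 and 2.17. Median percentiles were 33.1, 30.2 and 25.8 (permutation test against random lists, adjusted p = 0.20, 0.022 and 0.025). Ranked by the p of the best peak, the direction turned: the median percentiles of 84.5, 88.9 and 69.1 were above random lists in all 3 replicates (permutation test, adjusted p = 0.00075, 0.0010 and 0.0447). In replicates 1 and 3 alone the deficit did not pass the threshold (Fisher's exact test, adjusted p = 0.65), nor did it against only the genes named in the list of replicate 1 or 3 (adjusted p = 0.77). Among the genes of those lists with a KEGG annotation, which leave out genes that only replicate 2 holds, the term oxidative phosphorylation, tested after the data were seen, had 34 of 46 genes in all 3 lists (73.9%, odds ratio 0.995, Fisher's exact test, adjusted p = 1.0). No list held a peak on the mitochondrial chromosome, so the 15 mitochondrially encoded genes, such as mt-Atp6 and mt-Atp8, could not be tested.

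Synaptic and activity-regulated gene lists did not pass the test of presence. All 55 excitatory postsynapse genes had a peak in some list and 43 had one in all 3 (78.2%, odds ratio 1.99, 1.03 to 4.15, Fisher's exact test, adjusted p = 0.0728). Best log2 folds of Kalrn, an exchange factor of dendritic spines, were 3.14, 3.61 and 3.51. Those of Iqsec1 were 2.58, 4.18 and 3.12, and those of Epb41l1, which links receptors to the cytoskeleton, were 3.19, 4.71 and 2.38. This list passed the threshold in 9 of 16 alternatives, among them peaks under 1e-5 (Fisher's exact test, adjusted p = 0.0092) and peaks at the same place in all 3 lists (adjusted p = 0.0011), and not against random lists matched on gene span (permutation test, adjusted p = 0.53). Presynaptic release genes numbered 37 of 53 in all 3 lists (Fisher's exact test, adjusted p = 0.59). Beside Dnm1, they included Nrxn2, a neurexin, at 2.71, 4.11 and 2.95, Unc13c, a vesicle priming factor, at 4.28, 2.49 and 3.13, and Pclo, of the active zone, at 2.60, 2.52 and 4.19. GABAergic synapse genes numbered 24 of 30 (Fisher's exact test, adjusted p = 0.16), with Slc32a1, the vesicular GABA transporter, at 1.99, 2.99 and 1.89, Nlgn2 at 1.99, 2.37 and 2.21, Dlx1 at 1.87, 2.29 and 2.06, and Gabra5 at 1.76, 2.85 and 1.56. Activity-regulated genes numbered 26 of 31 (odds ratio 2.89, Fisher's exact test, adjusted p = 0.0591), and this list passed the threshold in 6 of 16 alternatives. Bdnf, a neurotrophin, had 4.46, 2.84 and 3.11, Per1 had 4.12, 3.47 and 2.23, Ier5 had 3.66, 2.35 and 3.43, and the postsynaptic scaffold gene Homer1 had 2.07, 2.99 and 2.26. By the rank of best fold, excitatory postsynapse genes were higher than random lists in replicate 2 (median percentile 72.7, permutation test, adjusted p = 0.0060) and not in replicates 1 and 3 (61.7 and 60.1, adjusted p = 0.20 and 0.29). Activity-regulated genes were likewise higher in replicate 2 (76.6, permutation test, adjusted p = 0.0105) and not in replicates 1 and 3 (46.2 and 40.9, adjusted p = 0.86 and 0.47), and presynaptic and GABAergic genes passed in no replicate. By the p of the best peak, excitatory postsynapse, presynaptic and GABAergic genes ranked higher than random lists in all 3 replicates, with mean median percentiles of 82.4, 85.8 and 71.7. A p can also follow the number of reads and the length of a peak. Respiratory chain genes, with lower median percentiles by fold, ranked higher by p too, so this order is not one of fold.

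Actin turnover, the list that holds Cap1, was not called in either direction. Of 68 members with a peak, 41 had one in all 3 lists (60.3%, 47.7 to 72.0, odds ratio 0.84, 0.50 to 1.42, Fisher's exact test, adjusted p = 0.61). Best log2 folds were 2.19, 3.86 and 2.20 for Eps8, an actin capping and bundling protein, and 2.33, 2.83 and 2.31 for Ssh2, a phosphatase of cofilin. For the kinase gene Pak2 they were 2.55, 3.56 and 1.74, and for Cyfip1, of the WAVE complex, 2.16, 2.61 and 2.32. The list's median percentiles of best fold were 27.1, 49.1 and 36.2, lower than random lists in replicate 1 (permutation test, adjusted p = 0.0060) and not in replicates 2 and 3 (0.97 and 0.13). Their mean of 37.5 turned to 68.2 when genes were ranked by the p of the best peak, and to 52.2 by the number of peaks. Against all 21887 protein-coding genes rather than those with a peak, actin turnover genes were more often in all 3 lists (log2 odds ratio 1.22, Fisher's exact test, adjusted p = 0.00077), as were 11 of the fixed lists in all. That background includes genes with no peak in any list.

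The m6A machinery had 15 of 23 members in all 3 lists (Fisher's exact test, adjusted p = 1.0). After Rbm15, the highest were Wtap, a methyltransferase complex subunit, with best log2 folds of 4.25, 3.15 and 3.84, Zc3h13, of the same complex, with 2.61, 3.13 and 2.37, and Ythdc1, a nuclear m6A reader, with 2.06, 3.14 and 2.0.

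Among cell type markers, those of vascular and meningeal cells were less often in all 3 lists, 6 of 19 (odds ratio 0.255, 0.079 to 0.720, Fisher's exact test, adjusted p = 0.0190). Abcb1a and Ly6a were among the 3 members without a peak. Kcnj8, of pericytes, had 2.88, 2.83 and 2.63, Flt1 and Cldn5, of endothelium, had 2.33, 2.90 and 2.88 and 2.37, 2.59 and 2.04, and Tagln, of smooth muscle, had 2.43, 1.61 and 1.92. This call was lost without replicate 2 (Fisher's exact test, adjusted p = 0.77). Cortical excitatory neuron markers numbered 14 of 18 (Fisher's exact test, adjusted p = 0.44), with Cux2 at 3.78, 3.06 and 2.85, Bcl11b at 2.58, 2.51 and 2.68, and Foxp2 at 2.07, 2.42 and 3.25. Astrocyte markers numbered 16 of 20 (Fisher's exact test, adjusted p = 0.28), with Glul, glutamine synthetase, at 3.99, 3.10 and 3.24, Fgfr3 at 2.36, 3.51 and 2.02, Slc1a2, a glutamate transporter, at 1.61, 3.77 and 1.86, and Sox9 at 1.48, 3.55 and 1.90. Oligodendrocyte lineage markers numbered 14 of 21 (Fisher's exact test, adjusted p = 1.0), with Pdgfra at 2.59, 2.93 and 2.61, Olig2 at 1.96, 3.32 and 1.92, Olig1 at 1.59, 4.35 and 1.33, and Sox10 at 1.42, 2.98 and 1.46. Their median percentiles were 17.7 and 21.4 in replicates 1 and 3 (permutation test, adjusted p = 0.0142 and 0.0246) but 71.1 in replicate 2 (adjusted p = 0.13), and their mean of 36.7 turned to 63.1 by the p of the best peak. Microglia and macrophage markers numbered 9 of 18 (Fisher's exact test, adjusted p = 0.33), with Csf1r at 2.29, 2.49 and 2.43, Tmem119 at 1.52, 2.98 and 0.91, and Itgam at 1.29, 1.47 and 2.04. Microglial median percentiles were 31.1, 38.6 and 16.3, lower than random lists in replicate 3 alone (permutation test, adjusted p = 0.30, 0.44 and 0.0240).

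**Figure D2:**
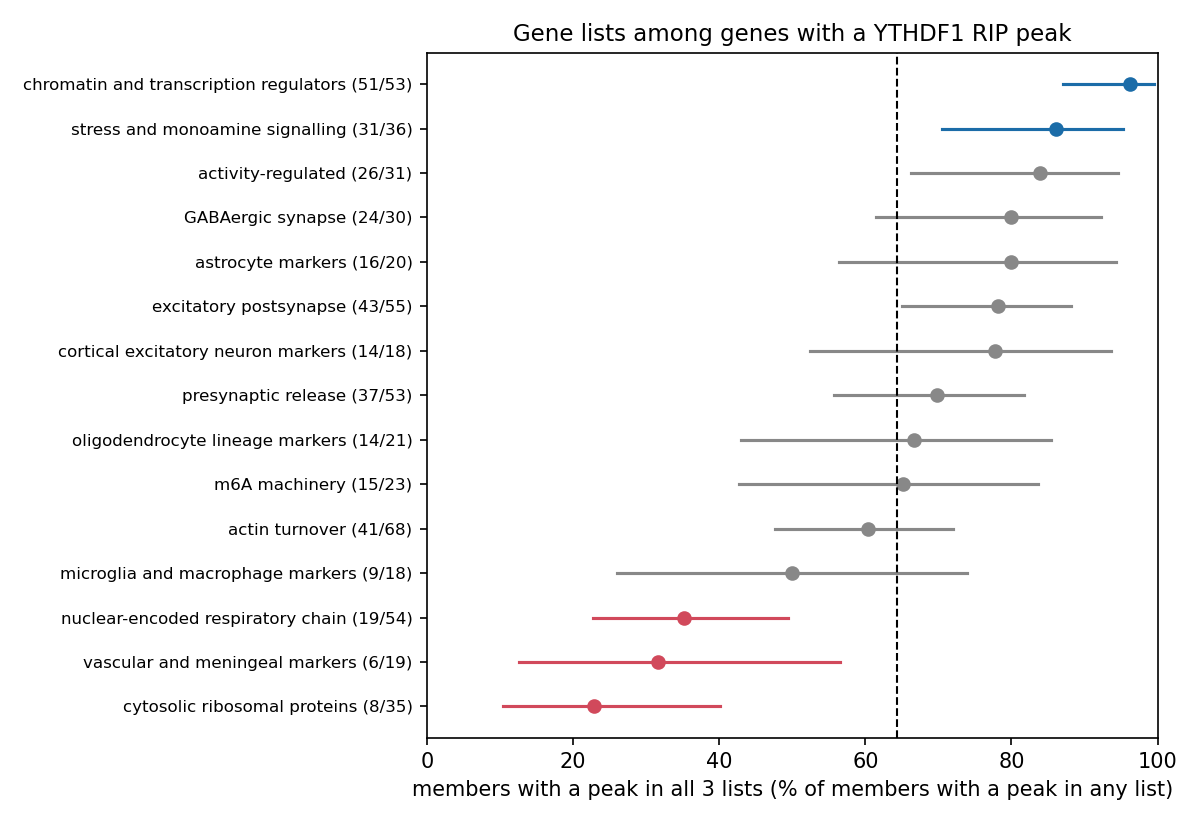
Share of each fixed gene list's members with a peak in all 3 lists, in percent of members with a peak in any list. Points are shares, bars are exact 95% binomial intervals, and counts stand beside the names. The dashed line is the same share, 64.4%, for all protein-coding genes with a peak in any list. Chromatin and stress lists (blue) lie above the line, and ribosomal, respiratory chain and vascular lists (red) below it.

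Over the 15 lists tested for presence, 2 were higher, 3 lower and 10 not called. By the rank of best peak fold against random lists, 0 lists passed in all 3 replicates after adjustment, and 2 did so at an unadjusted p under 0.05. Fold ranks were shared by replicates 1 and 3 and hardly with replicate 2. Across genes, which are not independent replicates, the Spearman correlation of best peak fold was 0.711 for replicates 1 and 3 (9859 genes), 0.046 for replicates 1 and 2 (8940 genes) and 0.036 for replicates 2 and 3 (8987 genes). The fold of replicate 2 is a different measure from that of the other lists. By the p of the best peak the correlation was 0.930 for replicates 1 and 3, 0.348 for 1 and 2 and 0.336 for 2 and 3, and by the number of peaks per gene it was 0.647, 0.286 and 0.265.

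**Figure D3:**
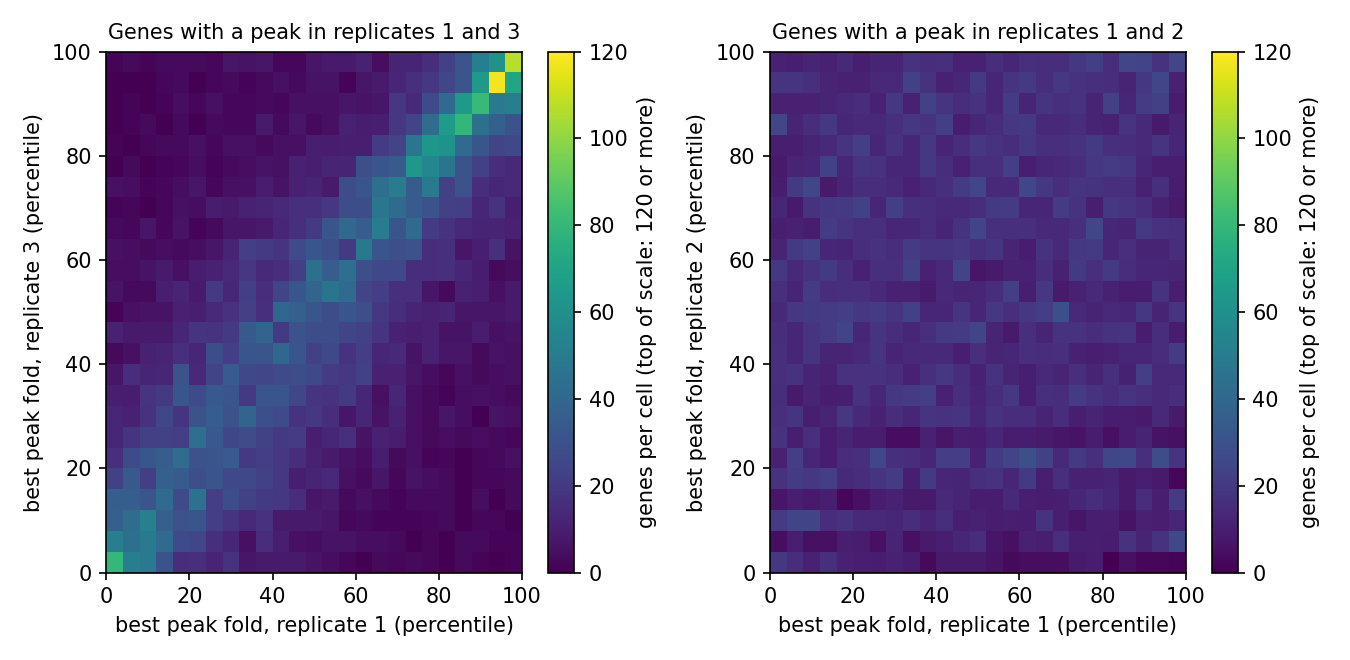
Genes by the percentile of their best peak fold in replicate 1 (x axis) and replicate 3 (y axis, left panel) or replicate 2 (y axis, right panel); colour is the number of genes per cell of the grid. Genes gather along the diagonal for replicates 1 and 3 (Spearman 0.711) and spread over the square for replicates 1 and 2 (0.046).

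In replicates 1 and 3, peaks lay mostly at the 3' end of transcripts. By the region labels in the lists of replicates 1 and 3, 45.7% and 45.6% of peaks were in the 3' UTR and 13.0% and 13.4% over the stop codon. Together these made 58.6% (exact 95% interval 58.0 to 59.2) and 59.0% (58.5 to 59.6). Coding exons held 24.8% and 24.1%, start codons 5.75% and 5.35%, 5' UTRs 2.61% and 2.73%, introns 2.0% and 2.16%, and exons of non-coding RNAs 5.93% and 6.27%. Under 1e-5 the mean share at the stop codon or in the 3' UTR was 69.8% over these lists; that of replicate 2 carries no region labels. Position along the gene span was taken for 26493, 31633 and 26552 peaks of replicates 1, 2 and 3. These lay inside protein-coding genes whose strand the lists of replicates 1 and 3 give, so genes that only replicate 2 holds are left out. Of these peaks, the last 10% of the span held 46.7%, 35.2% and 47.1% in replicates 1, 2 and 3. The first 10% held 15.6% of them in replicate 2 (15.2 to 16.0), against 4.80% (4.54 to 5.06) and 4.90% (4.64 to 5.16) in replicates 1 and 3. Under 1e-5 this share was 27.2% in replicate 2, against 2.57% and 2.59%. The strongest Ythdf1 peak of replicate 2 is an example. These shares were not set against the length of exons in each part of the span, which was not used here.

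**Figure D4:**
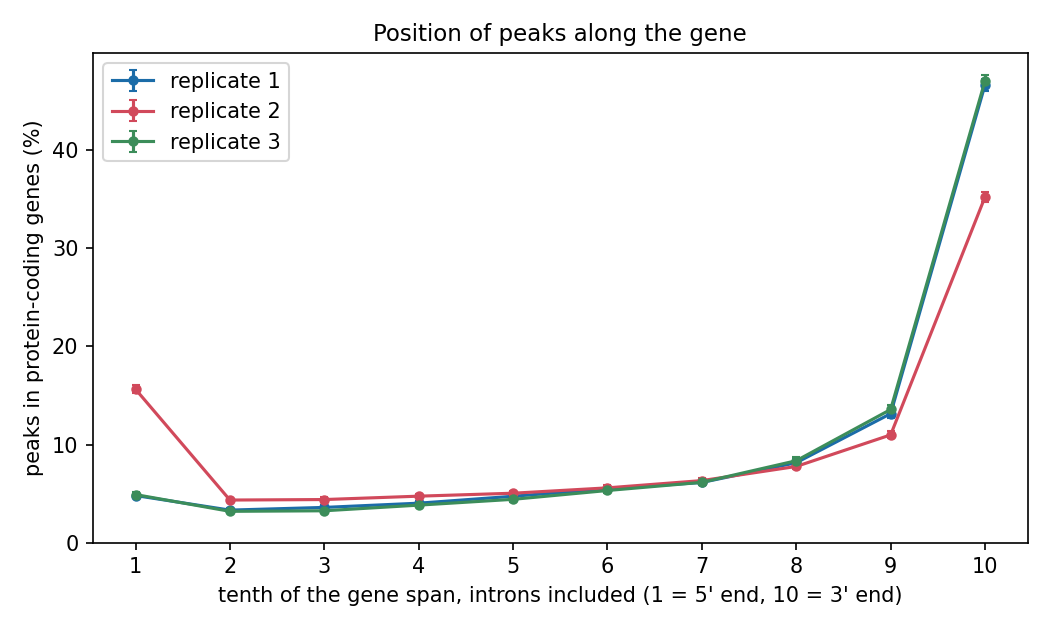
Share of peaks inside protein-coding genes whose strand the lists of replicates 1 and 3 give (y axis, percent; 26493, 31633 and 26552 peaks of replicates 1, 2 and 3) in 10 equal parts of the gene span from the 5' to the 3' end, introns included (x axis), by peak centre in replicates 1 and 3 and by summit in replicate 2; bars are exact 95% binomial intervals. The last 10% of the span holds 46.7%, 35.2% and 47.1% of peaks, and replicate 2 has a further 15.6% in the first 10%.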

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

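Except for the overlap of 5' peaks and the comparison of ribosomal protein genes with and without pseudogenes, the tests of explanations below were chosen after the result was seen.

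A signal outside the comparisons of the report appeared in non-coding genes: 96 long non-coding genes that overlap no protein-coding gene had a peak in the lists of replicates 1 and 3 and a replicate 2 summit in their span. The highest by mean log2 fold, named here after their values were seen, were Gm17747 with 3.46 and 6.48 in replicates 1 and 3, Gm9866 with 6.57 and 2.86, and Cep83os with 4.06 and 4.11. In all, 3777 peaks of replicate 2, 9.43% of its list, had their summit in no protein-coding gene.

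Best peak folds ranked genes alike in replicates 1 and 3 and not in replicate 2. Weak peaks alone do not account for this, though they may have a part. Over peaks under 1e-5 in every list, the Spearman correlation of replicates 1 and 2 rose from 0.046 to 0.194. That of replicates 1 and 3 rose from 0.711 to 0.830. As to tissue other than brain, 92.7% of excitatory postsynapse genes (51 of 55) had a peak in replicate 2, against 50.7% of other protein-coding genes (Fisher's exact test, p = 2.5e-11). That argues against tissue that lacks these transcripts. The comparison was not matched on gene span, and it cannot exclude other neural tissue or a mixture. Another fold measure or caller stays open. Ranked by the p of the best peak the correlation of replicates 1 and 2 was 0.348, against 0.930 for replicates 1 and 3, but the kind of list and the replicate change together, so they cannot be told apart, and a difference between animals was not tested.

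Among peaks in protein-coding genes whose strand the lists of replicates 1 and 3 give, replicate 2 also had more near the 5' end. These were 15.6% in the first 10% of the span, against 4.80% and 4.90% in replicates 1 and 3. Weak peaks of replicate 2 do not explain this, because under 1e-5 the share was 27.2%, against at most 2.59% in the other replicates. Among peaks of 1000 bp or less the share in replicates 1 and 3 reached 6.62%, against 16.3% in replicate 2, so short peaks differed too. Longer peaks, 45.0% and 46.0% of the lists of replicates 1 and 3, were left out there rather than placed again. Displaced centres of long spliced peaks therefore stay open. Sites that only replicate 2 has stay open: of the 2812 such peaks of replicate 2 under 1e-5 in the first 10% of the span, 19.4% overlapped a peak of 1000 bp or less of replicate 1 or 3, against 40.6% of those in the last 10%, but a lower overlap follows from the few peaks that replicates 1 and 3 have there. Whether the library of replicate 2, its caller or another part of the brain gave these peaks was not tested.

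Ribosomal protein and respiratory chain genes were fewer, and chromatin genes more, among genes with a peak in all 3 lists. With genes that have a peak in any list as background, gene span alone, introns included, does not account for this. Transcript length and abundance were not matched, so both stay open for these gene groups, chromatin genes included. Random lists matched on span held 17.1, 30.3 and 38.7 members in all 3 lists, against 8, 19 and 51 observed (permutation test, adjusted p = 0.0158, 0.0158 and 0.0030, the last the smallest 10000 draws can give after adjustment). For the respiratory chain that background draws on replicate 2, which held 49 of the 70 members, against 22 and 26 in replicates 1 and 3. Against only genes named in the list of replicate 1 or 3, the respiratory chain deficit did not pass the threshold, as given above. Too few reads stays open for both lists, since ranks by the p of the best peak (median percentiles of 84.5, 88.9 and 69.1 for the respiratory chain, all above random lists, and 18.2, 77.8 and 21.8 for ribosomal proteins, above them only in replicate 2) cover only members with a peak, and abundance in the input was not used here. Reads shared with pseudogenes stay open too, as 44.8% of ribosomal protein genes with a named pseudogene had a peak, against 45.0% of the others (Fisher's exact test, p = 1.0). The calls other than that of ribosomal proteins end without replicate 2, and no biological explanation was tested.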

How the results depend on the processing

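No paired analysis was possible because each list already sets an IP library against its own input and the lists analysed here hold no values per library. Not run, as they need a genome, exons or values per library not used here, were the m6A motif, random placement in exons, genes and regions from reference exons, and all tests of IP against input per gene; the region labels give no value for replicate 2, so leaving it out changes nothing there. Of the alternatives below, a q under 0.05 in every list, peaks of 1000 bp or less, other gene assignments for replicate 2, genes named in the list of replicate 1 or 3 as background, genes with any peak as the universe of the expectation, and correlations by p, q or number of peaks were chosen after seeing the data. Depth is unknown, so what it limits cannot be given. Where a value changed, the cause was not tested unless fewer peaks or genes entered by construction.

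Overlap of peaks stayed above random placement for all 3 pairs under every alternative run, from 7.82% against 1.45% at reciprocal overlap of 50% (replicates 2 and 3) to 84.3% against 38.1% under 1e-5 (replicates 1 and 3). Genes in all 3 lists exceeded independent lists without strata (3.19 times) and among genes with any peak (1.13 times). Stricter peaks lowered the counts by construction. The higher-fold 50% of each list left 14232, 20020 and 14315 peaks, 4350 genes in all 3 lists, 60.7% of peaks at the stop codon or 3' UTR and 0 lists with a Cap1 peak. A fold of 4 or more left 5219, 12997 and 5131 peaks, 1330 genes, 61.7%, Cap1 in 0 lists, Ythdf1 in 1 list and 1 gene list called. Under 1e-5 there were 14438, 12594 and 15000 peaks, 4227 genes, 69.8%, Cap1 in 0 lists and 3 gene lists called. At a q under 0.05, replicate 2 had 22154 peaks and Cap1 a peak in 2 lists.

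The 5 gene lists called for presence became 12 with all protein-coding genes as background, 2 with genes named in the list of replicate 1 or 3 as background, and 9 with peaks at the same place in all 3 lists. Leaving out each replicate gave 1 to 7, the 1 being ribosomal proteins without replicate 2, and 8940 to 9859 genes. Chromatin genes kept their call in 15 of 16 alternatives, ribosomal proteins in 15, respiratory chain in 11, vascular markers in 9 and stress and monoamine signalling in 6. By rank, 0 lists called became 5 by the p of the best peak (excitatory postsynapse, presynaptic, GABAergic, respiratory chain and astrocyte genes, all higher), 1 by the number of peaks per gene, and 0 to 3 on leaving out each replicate; without replicate 2 these were chromatin genes higher and ribosomal and oligodendrocyte genes lower.

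Log2 odds ratios of presence that changed sign were mostly those of lists not called. For actin turnover they were 1.22 with all protein-coding genes as background, 0.26 under 1e-5 and, on leaving out each replicate, -1.13 to 0.31, the latter without replicate 3. For microglia they were 0.53 with all protein-coding genes as background, 0.16 at a fold of 4 or more and -1.21 to 0.33 on leaving out each replicate, the latter without replicate 2. For m6A machinery they were -0.054 at equal list lengths, -0.60 with genes of list 1 or 3, -0.0094 matched on gene span and -0.34 (without replicate 1) to 0.50 on leaving out each replicate. For GABAergic synapse they were -2.73 at a fold of 4 or more and -0.17 in the higher-fold 50%. For presynaptic release they were -0.11 in at least 2 lists, -0.017 matched on gene span and -0.040 (without replicate 2) to 0.68 on leaving out each replicate. For oligodendrocytes they were -0.89 at a fold of 4 or more, -0.995 in the higher-fold 50%, -0.31 with genes of list 1 or 3, -0.35 at the same place, -0.0083 with replicate 2 summits counted for every gene and -0.73 (without replicate 2) to 0.75 on leaving out each replicate. Vascular markers, called lower, stood at 1.38 at a fold of 4 or more (Fisher's exact test, adjusted p = 0.31). Values matched on gene span are log2 of observed over expected members. Over the alternatives, adjusted p-values ran from 5.3e-18 to 0.14 for chromatin genes, 1.3e-07 to 0.35 for ribosomal proteins, 1.0e-09 to 0.77 for the respiratory chain, 0.0050 to 0.77 for vascular markers, 1.3e-07 to 1.0 for stress genes, 2.7e-08 to 0.77 for excitatory postsynapse and 0.00077 to 0.96 for actin turnover.

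Mean median percentiles crossed that of random lists by the p of the best peak for actin turnover (68.2), GABAergic synapse (71.7), respiratory chain (80.8), oligodendrocytes (63.1) and vascular markers (25.8). By the number of peaks they did so for actin turnover (52.2), GABAergic synapse (52.2), activity-regulated (40.4), stress (41.8) and vascular genes (24.9), and without replicate 2 for activity-regulated genes (43.5 to 61.4 on leaving out each replicate) and astrocytes (48.3 to 56.5). Spearman correlations of replicates 1 and 2, 1 and 3, and 2 and 3 were 0.348, 0.930 and 0.336 by the p of the best peak, 0.286, 0.647 and 0.265 by the number of peaks per gene and 0.194, 0.830 and 0.187 under 1e-5. Over overlapping peaks they were 0.122, 0.613 and 0.049, and 0.122 and 0.115 for replicates 1 and 2 and 2 and 3 at a q under 0.05.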

Other observations

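Pathways from the KEGG terms that the lists of replicates 1 and 3 attach to genes, tested after the data were seen, showed other groups. Of 295 terms with at least 10 genes among the 4594 annotated genes with a peak, 6 had more and 4 fewer members in all 3 lists (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted), and the overall share was 74.0%. More often present were genes of aldosterone synthesis and secretion, 66 of 71 (odds ratio 4.71, Fisher's exact test, adjusted p = 0.0088), and of phosphatidylinositol signalling, 80 of 88 (3.57, adjusted p = 0.0108). Autophagy had 96 of 108 by the same Fisher's test (2.86, adjusted p = 0.0124), adrenergic signalling in cardiomyocytes 91 of 102 (2.96, adjusted p = 0.0124), insulin secretion 51 of 55 (4.53, adjusted p = 0.0245) and inositol phosphate metabolism 62 of 69 (3.15, adjusted p = 0.0423). How many genes these terms share was not counted, and the tests of terms were not matched on gene span.

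Fewer members in all 3 lists were found for the ribosome, 27 of 58 (odds ratio 0.300, Fisher's exact test, adjusted p = 0.0036), complement and coagulation cascades, 11 of 27 (0.239, adjusted p = 0.0124), protein digestion and absorption, 14 of 30 (0.305, adjusted p = 0.0423), and systemic lupus erythematosus, a term rich in histone genes, 17 of 35 (0.328, adjusted p = 0.0423). Oxidative phosphorylation, with 34 of 46 (0.995, Fisher's exact test, adjusted p = 1.0), was not called, nor was the fixed list of respiratory chain genes against the genes named in the list of replicate 1 or 3 (adjusted p = 0.77). By the rank of best peak fold (permutation test against random lists), 0 terms passed in all 3 replicates after adjustment, and 7 did at an unadjusted p under 0.05. Without replicate 2 these terms were not tested again, and the annotation covers no gene that replicate 2 alone holds.

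Genes outside the protein-coding set numbered 1307 and 1343 in the lists of replicates 1 and 3, with 1014 in both. Of these, 664 were long non-coding by the lists' own biotype, and 451 of them had a replicate 2 summit in their span. Without strand in the library kit or in the list of replicate 2, signal in such a gene and in a gene that overlaps it could not be separated.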
